A study of Mus musculus with 3 samples.

How the data were processed

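The series measured total RNA from lungs of mice bearing B16 tumours, of mice bearing LLC tumours and of normal mice on 3 Affymetrix mouse expression arrays, 1 per group. Per the labels' protocols, RNA was isolated from frozen tissue with TRIzol and made into biotin-labelled cRNA by the standard procedure of the manufacturer. The groups of the tumour-bearing lungs were taken from the sample titles and that of the control lung from its source name. The array software, its version and the way probes were summarised are not given in the sources used here.

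The deposited values are intensity values on a linear scale, 1 per probe set and array, and negative values show that background had been subtracted. In each deposited column the mean without the lowest and highest 2% of values was 100.1, so the columns appear to have been scaled by 1 factor per array before deposit; no label records that step. Values ran from −722 to 7578.5, −609.5 to 7213.5 and −448.1 to 6206.2 on the B16-bearing, LLC-bearing and control array. Arrays carry no read depth; the number of arrays limits the precision.

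Of the 12488 probe sets, 66 manufacturer controls were used only for the 3' to 5' ratios. Gene names came from GEO's platform annotation, which gives 1 symbol for 10833 of the other 12422 probe sets, several for 396 and none for 1193. Of the single symbols, 10817 were found by gene ID in a RefSeq gene table (assembly GRCm38.p6, used for names only) and 0 needed an update. Probe sets with several symbols or none were counted but not named. A gene was represented by its brightest probe set (8251 genes). No genome positions are given, because the sources name no build for the values.

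Each array was multiplied by 1 factor that set the median log2 ratio to the control array to 0 over the brighter part of the probe sets, those with a mean above the median (factors 0.987, 1.01 and 1). Values under the floor, the 40th percentile of all scaled values (23.6), were set to it before log2 was taken. A gene was measured in a comparison if it was above the floor on at least 1 of the 2 arrays. Where the dimmer side was below the floor, the fold is a lower bound, written as at least that many fold. Probe sets with a difference of at least 2-fold were counted. With 1 array per group there is no p-value, standard error or replicate check.

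Gene lists of cell types, pathways and other tissues (36 lists, 943 entries) were fixed before the data were examined. For each list the median log2 difference of its measured members was placed among the medians of 10000 random lists of equal size, matched on mean log2 level in 20 bins. The percentile describes these arrays and is no p-value. A list stood apart when its percentile was under 1 or over 99 in both tumour-bearing lungs in the same direction, or in the B16-bearing against LLC-bearing comparison. Lists with under 5 measured members got no percentile.

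Genes were named by a rule also fixed before the data were examined. It takes S100a8 and S100a9, the 10 genes higher and 10 lower in both tumour-bearing lungs with the largest value of the smaller difference (at least 2-fold), and for each model the 5 genes higher and 5 lower by at least 2-fold whose difference in the other model was under 1.5-fold. It adds the 5 genes with the largest difference each way between the models, and up to 4 members of each list that stood apart, by the mean of the differences from control. This gave 68 genes. Members of the lists with too few measured genes were named as well, and the closing section names further genes that were chosen after their values were seen.

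Because both tumour-bearing lungs are compared with 1 control array, 200 sets of 3 unchanged arrays were simulated. Their noise was drawn, in 40 bins of signal, from the difference of the B16-bearing and LLC-bearing array divided by the square root of 2, and the counts, covariance and correlation were computed as for the real arrays. This noise contains real differences between the models, so the simulated counts may be too high. The simulated robust SD of the LLC-bearing lung against control had a median of 0.443, above the observed 0.354. For 5 gene lists the members on one side of the control in both lungs were counted in a further 200 simulated sets, at each gene's mean over the 3 arrays. This step was added after the counts were seen. The members were those measured on the real arrays, and this filter by the floor was not repeated in the simulated sets. A gene above the floor on the control array alone could only be lower in both, and one below it there alone only higher. For S100a8 and S100a9 the difference was also placed among the differences between the models of the 500 probe sets nearest in brightness.

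The steps were tested on simulated arrays for the comparison of both tumour-bearing lungs with control, with 200 planted changes among the 12422 probe sets, all above a signal of 100 and 50 at each fold size. Of planted 4-fold changes 90.0% were called at least 2-fold in both, of 3-fold changes 86.0%, of 2-fold changes 28.0% and of 1.5-fold changes 8.0%, against 1.28% of the unchanged probe sets. For the comparison of the B16-bearing with the control lung, 100 lists of 25 genes were shifted by a known log2 amount: 2 passed the 99th percentile with no shift, 61 with 0.3 and 99 with 0.6.

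Alternative settings listed before the arrays were read were the values as deposited, quantile normalization, factors from the median of all probe sets, floors at the 20th and 60th percentile, a pseudocount of 16 without a floor, limits of 1.5-fold and 3-fold, genes in place of probe sets, the mean in place of the median and the mean over all probe sets of a gene. Floors at the 30th percentile and at a signal of 100, and counts without liver genes, were added after the data were seen. A log2 difference was taken as unmoved when it shifted by less than 0.407, the robust SD between the models, and a count when it stayed within 1.5 times. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.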

Results

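Lungs of mice carrying a subcutaneous tumour on the back were profiled with lungs of normal mice on Affymetrix mouse expression arrays. Per the series description, the design models lungs that respond to a distant primary tumour before tumour cells arrive there. The 3 arrays held 1 lung RNA sample from a mouse or mice bearing B16 tumours (a mouse melanoma line), 1 from LLC (Lewis lung carcinoma, a mouse lung tumour line) and 1 control, so there were no replicates and every difference below describes these arrays and not the conditions. The labels do not say how many animals each sample came from. After removal of 66 control probe sets, 12422 probe sets were compared. The deposited values had medians of 41.8, 44.4 and 44.5 in the B16-bearing, LLC-bearing and control lung, and 21.1%, 20.3% and 20.3% of values lay below 0. Above the floor of 23.6 lay 7303, 7539 and 7517 probe sets. The floor is a percentile of all values of the 3 arrays together and no detection call, so it fixes the total of these counts. The ratios of the 3' to the 5' control probe set were 1.56, 1.47 and 1.44 for beta-actin and 1.20, 1.001 and 0.957 for Gapdh. With 1 array per group, only 1 yardstick does not compare with the control array. It is the spread of the log2 difference between the B16-bearing and LLC-bearing lung (robust SD 0.41). The control array enters this spread through the scaling, the floor and the selection of probe sets. The spread holds real differences between the models as well as noise. Against control the robust SD was 0.434 in the B16-bearing and 0.354 in the LLC-bearing lung.

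The first question was which genes were higher or lower in both tumour-bearing lungs than in the control lung. S100a8 and S100a9, which encode the calcium-binding subunits of calprotectin, an abundant protein of neutrophils, were higher in both. The S100a8 signal was 1224 in the B16-bearing lung and 1810 in the LLC-bearing lung against 485 in the control lung, which is 2.53-fold and 3.73-fold higher (log2 differences of 1.34 and 1.90). The S100a9 signal was 866 and 1684 against 305, or 2.84-fold and 5.53-fold higher (1.51 and 2.47). Of 500 probe sets of similar brightness, 3.2% differed between the B16-bearing and LLC-bearing lung by as much as S100a8 differed between the B16-bearing and control lung, and 2.2% by as much as in the LLC-bearing lung; for S100a9 the shares were 2.8% and 1.6%. The study is known for these genes, and the sources used here do not say how it chose them. Their direction here is therefore not counted as independent evidence.

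The neutrophil and granule genes were higher as a group. Of 25 members measured in the B16-bearing lung against control 20 were higher, and of 26 in the LLC-bearing lung 23 were higher; 19 were above the control lung in both and 2 below it in both. Both lungs are compared with 1 control array. Unchanged arrays simulated with genes varying independently therefore also put a median of 8 members (3 to 16) above it in both. A shift of many genes on the control array itself is not covered by this. Mpo, Prtn3 and Il1r2 were below the floor on the control array alone, so they could only be higher in both. The simulated sets did not repeat this filter by the floor. The median log2 difference was 0.30 in the B16-bearing lung (percentile 99.81 among 10000 random lists of equal size and level) and 0.60 in the LLC-bearing lung (percentile 100). Ltf, which encodes the granule protein lactoferrin, had signals of 109 and 151 against 54.3. Il1r2, the decoy receptor for interleukin 1, had 47.9 and 87.4 against a control signal below the floor, at least 2.03-fold and 3.70-fold higher. Without S100a8 and S100a9 the medians were 0.30 and 0.58, at percentiles 99.7 and 100. With a higher floor, at the 60th percentile of all values or at a signal of 100, the B16-bearing median was 0.12 and the list no longer stood apart in both lungs.

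Acute-phase genes were also higher in both. Of 12 members measured in the B16-bearing lung against control 11 were higher, with a median of 0.52 (percentile 99.95), and of 17 in the LLC-bearing lung 16 were higher, with a median of 0.85 (percentile 100). In both lungs 11 were higher, against 4 (1 to 10) in simulated unchanged arrays, and 1 was lower. Saa3, Orm2, Crp and Hpx were below the floor on the control array alone, so they could only be higher in both. The simulated sets did not repeat this filter by the floor. Saa3, a serum amyloid A gene expressed outside the liver, had signals of 239 and 183 against a control signal below the floor, at least 10.1-fold and 7.76-fold higher. Orm2, an orosomucoid, was at least 1.91-fold and 3.12-fold higher. Hpx, which encodes hemopexin, and Fga, the fibrinogen alpha chain, are made mainly in hepatocytes and were at least 9.53-fold and 8.20-fold higher in the LLC-bearing lung; in the B16-bearing lung Hpx was 30.4, and Fga was below the floor there and in the control lung. Genes of the hepatocyte list were high in the LLC-bearing lung too, as given with that comparison.

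Fkbp5, a co-chaperone of the glucocorticoid receptor, was also among the genes with the larger differences in both lungs. Its signal was 323 and 192 against 24.6 in the control lung, just above the floor, 13.1-fold and 7.80-fold higher (3.71 and 2.96). Next to Saa3, the other genes of this group were Sprr2i, a small proline-rich protein of the cornified envelope, Krt6a, a keratin, Defb2, a beta-defensin, Tradd, an adaptor of the tumour necrosis factor receptor, Gss, the glutathione synthetase, Ifngr1, a chain of the interferon gamma receptor, Clec4f, a C-type lectin known from Kupffer cells, and Rbm4b, an RNA-binding protein. Sprr2i signals were 268 and 221 against 33.2, from a probe set that can bind related genes. Krt6a was 4.51-fold and 6.05-fold higher on its brightest probe set, while its second probe set read 78.6, 77.9 and 74.7 in the B16-bearing, LLC-bearing and control lung. The second probe set of Gss read 39.6, 28.1 and 30.4 in the same order, so it was not higher in the LLC-bearing lung, and the Tradd signal comes from a probe set whose name marks relaxed design rules. Tumour-lung signals of Defb2, Tradd, Gss, Ifngr1, Clec4f and Rbm4b lay between 77.6 and 149.9; the robust SD between the models was 0.53 for probe sets with signals from 50 to 100 and 0.44 from 100 to 200. With a floor of 100 the Fkbp5 differences were 1.69 and 0.94, while those of S100a8 and S100a9 did not move.

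In the other direction, Cbr2, a carbonyl reductase abundant in mouse lung, had signals of 70.0 and 52.5 against 782 in the control lung, 11.2-fold and 14.9-fold lower (−3.48 and −3.90; −2.97 in both with a floor of 100). Matn2, the matrix protein matrilin 2, had 42.8 and 26.9 against 186, while its second probe set was below the floor on all 3 arrays. Ptprn, a phosphatase-like protein of secretory vesicles, had 28.3 in the B16-bearing lung and a signal below the floor in the LLC-bearing lung against 186. Foxa2, a transcription factor of lung epithelium, was at least 4.74-fold lower in both, from a control signal of 112. Dhps, the deoxyhypusine synthase, was 4.68-fold and at least 6.15-fold lower, Atp2a2, the calcium pump of the sarcoplasmic reticulum, at least 4.61-fold lower in both, and Hlx, a homeobox gene, had 25.9 in the LLC-bearing lung and a signal below the floor in the B16-bearing lung against 103.7.

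B lymphocyte genes were lower in both tumour-bearing lungs. Of 13 measured members, 12 were below the control lung in both and 1 was above it in both. Simulated unchanged arrays put 4 (0 to 10) below it in both. Fcer2a, Cd72 and Blnk were above the floor on the control array alone, so they could only be lower in both. The simulated sets did not repeat this filter and do not cover a shift of many genes on the control array. The medians of the list were −0.48 (percentile 0.865) and −0.58 (percentile 0). Fcer2a, the low-affinity IgE receptor CD23, had a control signal of 120 and was at least 5.08-fold lower in both. Cd79a, a chain of the B cell receptor complex, was below the floor in the B16-bearing lung and at it, with 23.9, in the LLC-bearing lung, against 111.4 in the control lung. Pou2af1, a transcriptional coactivator of B cells, and Blnk, an adaptor of B cell receptor signalling, were at least 2.71-fold and 2.44-fold lower in the B16-bearing lung. With array factors taken from the median of all probe sets, or with the floor at the 60th percentile, the list no longer stood apart in both lungs.

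Muscle genes were lower in both as well. Of 24 measured members, 16 were below the control lung in both and 3 above it in both. Simulated unchanged arrays put 8 (1 to 14) below it in both. Tnnc1, Mb, Myl1 and Ckmt2 were above the floor on the control array alone, so they could only be lower in both. The simulated sets did not repeat this filter by the floor. The medians of the list were −0.65 and −0.84, both at percentile 0. Myh6, the cardiac alpha myosin heavy chain, had signals of 67.9 and 30.5 against 233 (−1.78 and −2.94). Tnnc1, the slow and cardiac troponin C, was at least 6.22-fold lower in both from a control signal of 147, and Mb, which encodes myoglobin, at least 3.19-fold lower in both. Pvalb, a calcium-binding protein of fast muscle, was 242.5 in the B16-bearing lung, 275.7 in the control lung and below the floor in the LLC-bearing lung on the probe set used, which is one of a pair whose other member was below the floor throughout.

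**Figure D1:**
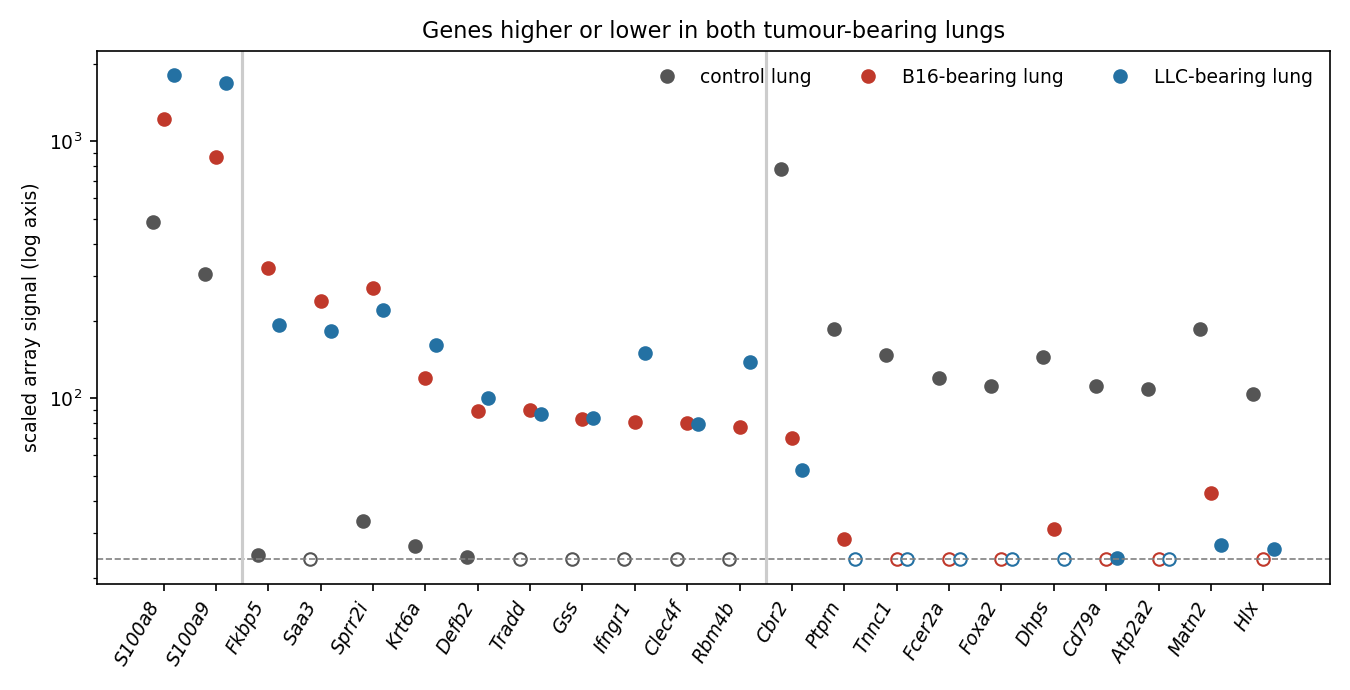
Scaled array signal (log axis) of S100a8, S100a9 and the 10 genes with the largest shared difference in each direction, 1 point per array, open points on the dashed line being below the floor of 23.6. S100a8 and S100a9 lie far above the floor on every array, while most other genes are near the floor on the dimmer side.

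By number, 97 probe sets were at least 2-fold higher in both tumour-bearing lungs than in the control lung and 101 at least 2-fold lower. In opposite directions 5 were at least 2-fold different, against a median of 4 (1 to 9) in simulated arrays with no change. Independent lists of these sizes would share 7.34 and 7.47 probe sets. Both comparisons use the same control array, and simulated arrays with no change, given the spread between the B16-bearing and LLC-bearing lung, shared a median of 158 higher (129 to 198 over 200 simulations) and 124 lower probe sets (94 to 149). Across the 8243 probe sets above the floor on any array, which are not independent replicates, the log2 differences had a correlation of 0.43 against 0.50 simulated and a covariance of 0.141 against 0.192, a difference of −0.0512. The count of 97 higher lay below its simulated range, the count of 101 lower within it, and the covariance below its range of 0.1732 to 0.2253. The simulated arrays also spread too widely for single comparisons. The robust SD of the LLC-bearing lung against control was 0.354, against 0.426 to 0.46 simulated, and its counts lay below their simulated ranges. So did the B16-bearing count of higher probe sets. The single control array may thus account for the whole excess over independent lists, but these simulations cannot settle it. As the simulated noise holds real differences between the models, the counts neither show sharing beyond the control array nor exclude it. Of the genes 2-fold higher in both that had a second measured probe set, 10 in all, the second probe set was higher in both for 6 and 2-fold higher in both for 0; of the 6 such genes that were lower, it was lower in both for 3 and 2-fold lower for 2. With a floor of 100 the counts were 9 higher and 12 lower.

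The second question was what each tumour-bearing lung showed alone. In the B16-bearing lung, Eif5a, a translation factor, had a signal of 245, Colq, the collagen tail of acetylcholinesterase, 230, Glns-ps1, a glutamine synthetase pseudogene, 148, Slc27a1, a fatty acid transporter, 129, and Ngef, a guanine nucleotide exchange factor, 128, with LLC-bearing and control signals all below the floor. These were at least 10.4-fold, 9.75-fold, 6.29-fold, 5.46-fold and 5.42-fold higher than in the control lung. Ephx1, the microsomal epoxide hydrolase, was below the floor in the B16-bearing lung against 165.5 in the LLC-bearing and 217.5 in the control lung, at least 9.22-fold lower than control. Josd2, a deubiquitinase, Bckdhb, a subunit of branched-chain keto acid dehydrogenase, Pold4, a subunit of DNA polymerase delta, and Ifitm10 were at least 5.56-fold, 4.58-fold, 4.46-fold and 4.37-fold lower. In number, 272 probe sets were at least 2-fold higher and 395 at least 2-fold lower in the B16-bearing lung than in the control lung. Simulated unchanged arrays gave medians of 386 (339 to 443) and 388.5 (337 to 429). With factors from the median of all probe sets, which moves the B16-bearing array by 0.11 on the log2 scale, the split was 342 higher and 314 lower. With a floor of 100 it was 41 and 44.

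In the LLC-bearing lung, hepatocyte genes were high. Alb, which encodes serum albumin, had a signal of 1327 and lay below the floor in the other two lungs, at least 56.2-fold higher. Mup5 and Mup3, major urinary proteins secreted by mouse liver, had signals of 1293 and 830; Mup5 was 38.4-fold higher than its control signal of 33.7 and Mup3 at least 35.2-fold higher, both on probe sets that can bind other family members. Of the 11 measured genes in the hepatocyte list, 11 were above the control lung, 8 of them at least 2-fold, with a median of 1.60 (percentile 100). Apoa1, the main protein of high-density lipoprotein, was 167 and below the floor in the other lungs, and Serpina1b, an alpha-1-antitrypsin gene, was 694 against 130 in the B16-bearing and 113 in the control lung. In the B16-bearing lung only 4 list genes were measured against control. Apart from these genes, Dct, the melanocyte enzyme dopachrome tautomerase, was 196 in the LLC-bearing lung and below the floor in the B16-bearing and control lungs.

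Genes lower in the LLC-bearing lung alone were Pvalb, at least 11.7-fold, Daglb, a diacylglycerol lipase, at least 8.43-fold, Man2c1, an alpha-mannosidase, at least 5.15-fold, Tcp11, a testis gene, at least 4.37-fold, and Mphosph9, a phosphoprotein of mitosis, at least 4.37-fold. Daglb had signals of 169 in the B16-bearing and 199 in the control lung. In number, 335 probe sets were at least 2-fold higher and 235 at least 2-fold lower in the LLC-bearing lung than in the control lung, against simulated medians of 387 (343 to 430) and 387 (344 to 442). Leaving out 94 probe sets of liver genes, a choice made after seeing the data, gave 304 higher and 235 lower, and a floor of 100 gave 56 and 23.

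**Figure D2:**
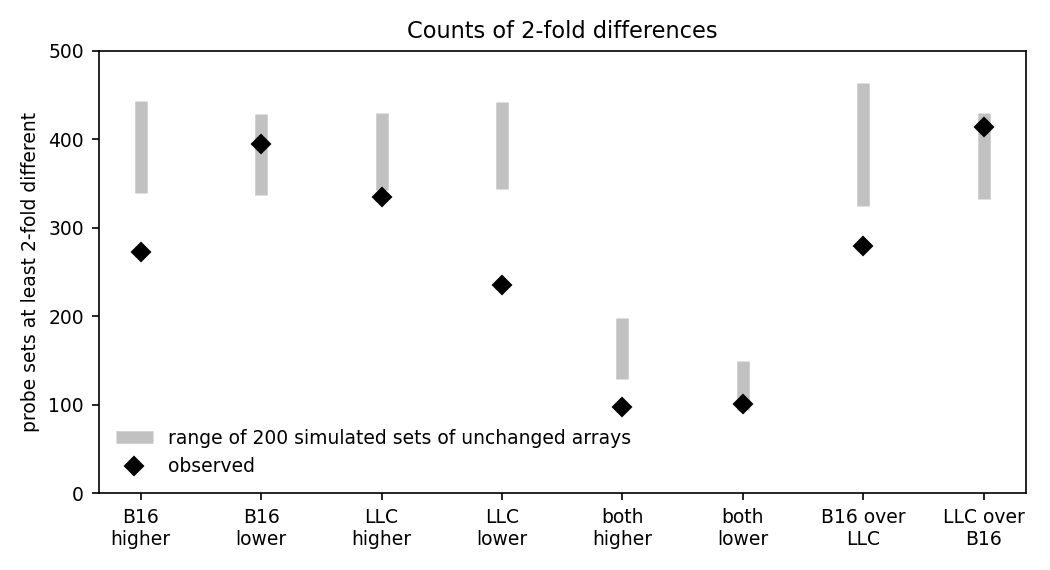
Number of probe sets at least 2-fold different (y axis, from 0) in each comparison and direction; diamonds are observed counts and grey bars the range over 200 simulated sets of unchanged arrays. The observed count of 97 higher in both lies below the simulated range of 129 to 198.

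The tumour-bearing lungs were also compared with each other. Here the control array entered only through scaling, the floor, the choice of the brightest probe set and the level matching of lists. Genes of macrophages and monocytes were lower in the B16-bearing than in the LLC-bearing lung. Ccr2, the chemokine receptor of inflammatory monocytes, had signals of 27.8 and 294 (−3.40), with 46.8 in the control lung. Ptprc, which encodes the leukocyte antigen CD45, had 24.98 and 245 (−3.29), with 137 in the control lung. In the B16-bearing lung both signals lay close to the floor of 23.6, and with a floor of 100 the differences were −1.55 for Ccr2 and −1.29 for Ptprc. A second Ptprc probe set was lower in the B16-bearing lung as well. The macrophage and monocyte list, which holds neither Ccr2 nor Ptprc, had a median of −0.42 (percentile 0). Of its 27 measured members 19 were lower, 7 of them at least 2-fold, and 8 were higher. Against control its medians were −0.11 (percentile 5.02) in the B16-bearing and 0.20 (percentile 99.52) in the LLC-bearing lung. Common reference genes shifted nearly as far between the models, as given below. Their middle member, B2m, was higher by 0.31 in the LLC-bearing lung than in the control lung. C1qa and C1qc, complement subunits made by macrophages, were 128 and 318 in the B16-bearing lung, 213 and 352 in the LLC-bearing lung, and 88.6 and 186 in the control lung. C1qb, from the same list, went the other way between the models, with 173 in the B16-bearing, 117 in the LLC-bearing and 143 in the control lung. Chil3, a chitinase-like protein of alveolar macrophages, was 288, 442 and 549.5 in the same order, and Fabp1, a fatty acid-binding protein also in the hepatocyte list, was above the floor in the LLC-bearing lung alone, at 71.7.

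The list of MHC class II and dendritic cell genes had a median of −0.31 (percentile 0.32), with 12 of 14 measured members lower in the B16-bearing lung and none 2-fold lower. Cd74, the invariant chain, was 2853 against 3100, H2-Eb1, a class II beta chain, 732 against 833, and Cd86, a costimulatory ligand, 40.1 against 68.0, while Flt3, a receptor of dendritic cell precursors, was 137 against 101. The neutrophil list was lower too, with a median of −0.48 (percentile 0) and 22 of 26 members lower. Common reference genes moved the same way: their median was −0.35 (percentile 0.385), with 8 of 11 lower. Their shift was larger than that of the MHC class II list and close to that of the macrophage and monocyte list. Shifts of this size are therefore not particular to these lists. Among them Actb, cytoplasmic actin, was 288 against 366, Pgk1, a glycolytic enzyme, 223 against 319, and Sdha, a subunit of succinate dehydrogenase, 46.2 against 70.8, while Tbp, the TATA-binding protein, was 26.4 against a signal below the floor. The MHC class II list no longer stood apart under quantile normalization, with the floor at the 30th percentile or with the mean in place of the median, and the reference genes no longer did with the mean or with all probe sets of a gene averaged.

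Higher in the B16-bearing than in the LLC-bearing lung were Lox, the collagen and elastin crosslinking enzyme lysyl oxidase, with 376 against 37.0 (3.34, 10.2-fold higher) and a second probe set at 262 against 95.1, and Pea15a, a regulator of ERK signalling, with 239 against a signal below the floor. Eif5a, Pvalb and Colq completed this group, at least 10.4-fold, 10.3-fold and 9.75-fold higher. The muscle list had a median of 0.39 (percentile 99.99) with 14 of 20 measured members higher; with the floor at the 30th percentile it was 0.16 and no longer stood apart. The hepatocyte list had a median of −1.60 (percentile 0), 9 of its 11 members being at least 2-fold lower in the B16-bearing lung. In number, 279 probe sets were at least 2-fold higher and 414 at least 2-fold lower in the B16-bearing than in the LLC-bearing lung. The split was 366 and 344 with factors from the median of all probe sets, 279 and 385 without liver genes, and 37 and 78 with a floor of 100.

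**Figure D3:**
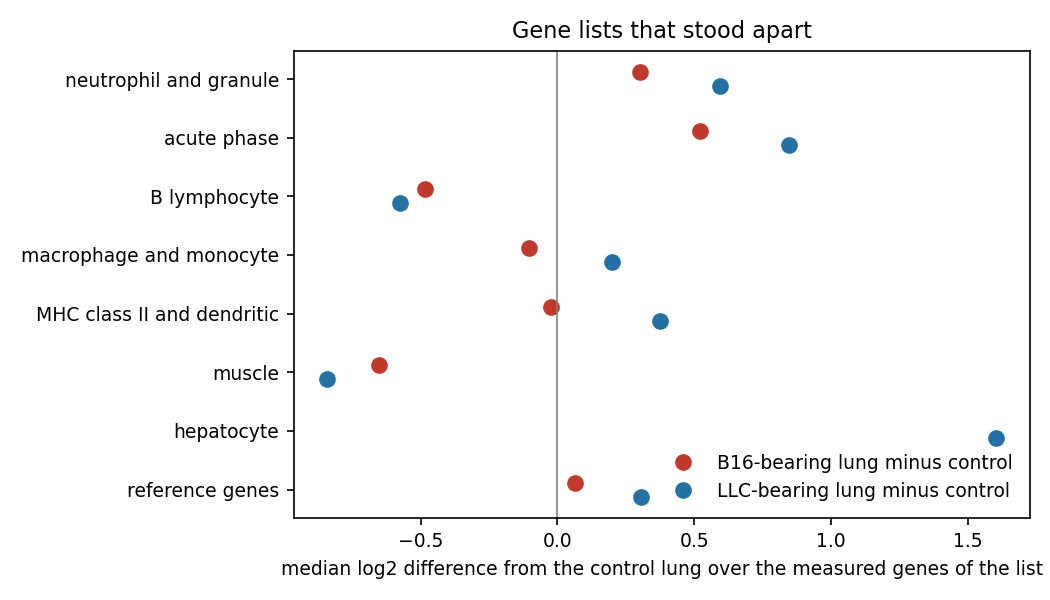
Median log2 difference from the control lung (x axis) over the measured genes of the 8 lists that stood apart, 1 point for each tumour-bearing lung; the hepatocyte list had too few measured genes for a B16-bearing median. The B lymphocyte and muscle medians lie below 0 in both lungs (−0.48 and −0.58, −0.65 and −0.84).

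Of 36 gene lists, 8 stood apart and 2 had under 5 measured members. Close to the limit, with medians in the B16-bearing and LLC-bearing lung against control, were genes tied to the metastatic niche (0.28 at percentile 99.72 and 0.17 at 98.69), which hold S100a8, S100a9 and Saa3, extracellular matrix remodelling genes (0.23 at 99.63 and 0.16 at 98.45) and red blood cell genes (0.22 at 95.54 and 0.42 at 99.99). Only the LLC-bearing lung lay above the 99th percentile for chemokines and their receptors (0.36 against 0.03), interferon-responsive genes (0.32 against −0.02) and metallothionein and glucocorticoid-responsive genes (0.27 against 0.14). The reference genes were shifted by a similar amount: their middle member was 0.31 in the LLC-bearing lung (B2m) and 0.06 in the B16-bearing lung (Pgk1). LLC-bearing medians of this size are therefore not particular to these lists. Below the 1st percentile lay oxidative phosphorylation genes in the B16-bearing lung alone (−0.28 at 0.01 against −0.06 at 12.24) and clock genes in the LLC-bearing lung alone (−0.28 at 0.66 against −0.11 at 24.12). Between the B16-bearing and LLC-bearing lung these lists stayed within the limits, at percentiles 1.8 for chemokines, 5.725 for interferon, 98.67 for metallothionein and glucocorticoid genes, whose median was higher in the B16-bearing lung by 0.21, 2.75 for oxidative phosphorylation and 49.56 for clock genes.

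The other lists had medians between −0.08 and 0.43 in both lungs and percentiles between 1 and 99. In the B16-bearing and LLC-bearing lung these were 0.10 and 0.18 for the S100 family, 0.04 and 0.18 for cytokines and their signalling, 0.24 and 0.06 for hypoxia and glycolysis, 0.10 and 0.19 for the cell cycle, 0.15 and 0.11 for immediate early genes and 0.09 and −0.00394 for heat shock genes. Endothelial genes had 0.04 and 0.0028, fibroblast genes 0.06 and −0.07, type 2 alveolar cells 0.04 and 0.03, type 1 alveolar cells −4.94e-05 and −0.08, and airway epithelium 0.10 and −0.04. T and NK cell genes had 0.07 and 0.22, eosinophil and mast cell genes 0.05 and 0.25, thymus and lymph node genes 0.43 and 0.04, and adipocyte genes 0.05 and 0.20. The adipocyte median hides members that moved apart, named after their values were seen. Car3, Adipoq and Fabp4 were 68.9, 37.0 and 82.8 in the B16-bearing lung against 284.8, 97.1 and 212.6 in the control lung. Lipe went the other way (123.7 against 44.2), and the other members differed by less. Fabp4 is also counted in the macrophage list. Complement and coagulation genes had 0.13 and 0.11 and ribosomal protein genes 0.0052 and 0.06. Melanocyte genes, markers of B16 cells, had −0.08 in the B16-bearing and −0.05 in the LLC-bearing lung. Of platelet genes, Vwf, the von Willebrand factor, was 732 and 537 against 354, Gp9, a platelet glycoprotein, 137 and 105 against 89.1, and Gp5 24.7 in the B16-bearing lung and below the floor otherwise. Of sex-linked genes, Eif2s3y alone was above the floor, with 36.4 and 41.3 against 68.0.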

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

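The tests on hepatocyte genes outside the acute phase and on smooth muscle split by lung, and the simulated counts of clock and cardiac genes, were chosen only after the result was seen. Further genes named here (Ttr, Apoh, Serpina1c, Cps1 and the other hepatocyte enzymes, Cdkn1a, Dbp and the clock genes) were chosen after their values were seen. The spread given with a median is its SD over resamplings of the genes, which are not replicates. For the hepatocyte enzymes and the further cardiac genes, the bounds written in advance did not include this spread.

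Mup5, Pea15a, Ccr2 and Ptprc were lower than control in one tumour-bearing lung and higher in the other, in each case by more than the robust SD of 0.41 between the models. The log2 difference of the B16-bearing from the LLC-bearing lung was −5.78 for Mup5, 3.34 for Pea15a, −3.40 for Ccr2 and −3.29 for Ptprc. The differences were not tested, since each group had 1 array. With a floor of 100 they were −3.69, 1.25, −1.55 and −1.29, and the opposite directions were lost for Mup5 and Ccr2 (0 in the B16-bearing lung against control) and for Pea15a (−0.33 in the LLC-bearing lung, under the robust SD), while Ptprc kept them (−0.45 and 0.84).

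Hepatocyte genes were high in the LLC-bearing lung only, with Mup5 among them; 4 of the 12 genes of that list on the array were also above the floor in the control lung, and 3 stand in another list. An acute-phase response in the lung is argued against only as the whole cause, by hepatocyte genes outside that response. They were higher in the LLC-bearing than in the B16-bearing lung by a median of 1.52 (14 measured, 11 at least 2-fold). Of the 14, 10 are genes in which the pattern was seen, so their height was known beforehand. The other 4 had a median of 1.31 (0.0941 to 1.71). The highest of these 4, Serpina1c, was read on a probe set that can bind other family members. Liver RNA in the LLC-bearing sample would be excluded by the bounds set in advance. The 18 measured hepatocyte enzymes were higher by a median of 0.197 at percentile 91.26, under the 0.2 and 95 set to exclude it. It is left open here, because the median lies under its bound by less than its spread (0.1245), which those bounds did not include. The median also cannot exclude a small share of liver RNA, since some of these enzymes had high control signals (Fmo1 869, Gstp1 864). Fbp1, Bhmt, Cyp2d9, Otc and Ugt2b5 were above the floor in the LLC-bearing lung alone, between 26.1 and 51.2. By the floor they could only be higher there. Slc10a1 was above it in the B16-bearing lung alone, at 42.1. Cps1, the urea cycle enzyme, at 248 against 41.2 in the B16-bearing and 49.7 in the control lung goes with liver RNA. Alb at 1327 does too, but it is part of the pattern to be explained. Ttr, an abundant liver transcript, at 20.3 and Apoh, an abundant plasma apolipoprotein, at −20.6 go against it. No liver sample on this array shows whether the probe sets of Ttr and Apoh respond. An effect of the tumour model also stays open, as untested.

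Cardiac muscle genes were lower in both tumour-bearing lungs, with medians of −1.15 and −1.26 over 14 measured genes, 12 of them lower in both, against 5 (0 to 10) in simulated unchanged arrays. These genes also stand in the muscle list, so this count is no separate support. Tnnc1, Mb and Ckmt2 were above the floor on the control array alone and could only be lower in both. The simulated sets did not repeat this filter. Fewer muscle cells of every kind is argued against in the B16-bearing lung, where smooth muscle genes had a median of 0.229 (spread 0.145). In the LLC-bearing lung their median was −0.190 (spread 0.157), which does not decide. Less heart or pulmonary vein muscle in the tumour-bearing samples may account for the pattern. Further cardiac genes, used because the first set had shown the pattern itself, had medians of −0.37 (14 measured, spread 0.328) and −0.162 (13 measured, spread 0.354). By the bound set in advance the LLC-bearing median would exclude this explanation. With the spread, which that bound did not include, these genes cannot be told apart from unchanged or from lower ones. An effect of the tumours is likewise untested.

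Fkbp5 and Cdkn1a, a cell cycle inhibitor, were higher and Dbp, a clock output gene, lower in both tumour-bearing lungs; Cdkn1a signals were 738 and 370 against 153, and Dbp was below the floor in the B16-bearing lung and 80.4 in the LLC-bearing lung against 186. A different clock phase at collection is a candidate explanation for the Dbp part, judged by direction and not by size. The 8 other measured clock genes used here came from the clock list scored above. Of these, 6 had the predicted direction in both lungs (Per2, Per3, Tef, Nr1d1 and Nr1d2 lower, Nfil3 higher). Arntl (0.68 and 0) and Clock (0.37 and −0.13) did not, and 0 went against it by 1.5-fold in both. Arntl was below the floor in the LLC-bearing and control lung. The prediction and the count left out Per1 (−0.11 and 0.14), Cry1 (0.46 and 0.08), Cry2 (0.14 and −0.36) and Bhlhe40 (−0.08 and 0.09), also measured in the clock list. Among these, Cry1 alone had the same sign in both lungs. In simulated unchanged arrays that share the control array, and in which genes vary independently, the median was 2 of the 8 (0 to 6). Of 200 such sets, 5 reached 6. Per3 (−0.31 and −0.20) and Tef (−0.34 and −0.40) differed by less than the robust SD of 0.41 between the models in both lungs. Per2 did so in the LLC-bearing lung (−0.35). Only Nr1d1, Nr1d2 and Nfil3 differed by more in both, so the count overstates how many genes clearly moved. A glucocorticoid response stays open, since 14 other responsive genes had medians of 0.132 (percentile 78.52) and 0.20 (percentile 98.82). The labels give no time of collection, and an effect of the tumours on either was not tested.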

How the results depend on the processing

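The floors at the 30th percentile and at 100 and the counts without liver genes were chosen after the data were seen. The planned floor at the 20th percentile was not run, since that value is −0.506 and has no log. No paired analysis was possible because each group had 1 array. Signal over background is one limit: the robust SD between the models was 0.47 for signals from the floor to 50, 0.53 from 50 to 100 and 0.22 above 1000.

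No difference of a named gene of at least 2-fold changed sign under any alternative. Of the values of named genes under the alternatives, 1209 moved by less than 0.407 and 423 by more, all under changed floors, the pseudocount or the mean over probe sets. The counts stayed within 1.5 times under every scaling, with the pseudocount, with genes and without liver genes (48 values).

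In the order B16-bearing higher and lower, LLC-bearing higher and lower, both higher and lower, and B16-bearing over and under LLC-bearing, the counts were 508, 763, 606, 529, 187, 231, 541 and 786 with the floor at the 30th percentile; 73, 88, 93, 48, 18, 25, 77 and 117 with it at the 60th; and 41, 44, 56, 23, 9, 12, 37 and 78 with it at 100. At 1.5-fold they were 787, 1119, 785, 742, 270, 350, 750 and 1067, and at 3-fold 80, 106, 115, 72, 35, 27, 87 and 146. The covariance of the differences from control was 0.229, 0.0697 and 0.0579 with those 3 floors. These shifts follow from the construction of the alternatives.

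Lists that no longer stood apart are given with their medians. The neutrophil list had 0.12 and 0.51 with the floor at the 60th percentile, and 0.12 and 0.51 with the floor of 100. The B lymphocyte list had −0.37 and −0.59 with factors from all probe sets, and −0.46 and −0.61 with the floor at the 60th percentile. Between the models, the MHC class II list had −0.20 under quantile normalization, −0.27 with the floor at the 30th percentile and −0.37 as a mean; the muscle list 0.16 with the floor at the 30th percentile; and the reference genes −0.29 as a mean and −0.29 with all probe sets averaged. The cause was not tested. The acute-phase, macrophage and hepatocyte lists stood apart under each alternative run.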

Other observations

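The genes below were chosen after their values were seen and are given as values. Mt1 and Mt2, the metal-binding metallothioneins, had signals of 508 and 1152 in the B16-bearing lung, 111 and 429.5 in the LLC-bearing lung and 118 and 266 in the control lung. Zbtb16, a transcription factor induced by glucocorticoids, had 859 and 630 against 308, while of other such genes Tsc22d3 had 49.96 and 46.1 against 63.7 and Sgk1 981 and 975 against 959.7. In the B16-bearing lung Eln, which encodes elastin, was higher than control by 1.97 on the log2 scale and Mmp3, a matrix metalloproteinase, by 1.22, against 0.47 and 0.16 in the LLC-bearing lung.

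Il1b, the cytokine interleukin 1 beta, was 182.5 in the LLC-bearing lung against 48.9 in the B16-bearing and 40.6 in the control lung, and Mmp9, the gelatinase of neutrophils, was 150 against 77.6 and 54.0. Ccl8, a monocyte chemokine, was higher than control by 2.28 on the log2 scale and S100a4, a motility-related S100 gene, by 1.99, against −0.03 and −0.72 in the B16-bearing lung. Slc4a1, the anion exchanger of red blood cells, was higher by 1.03 in the B16-bearing and 1.19 in the LLC-bearing lung, and Alas2, the erythroid enzyme of heme synthesis, by 0.65 and 0.89. Tyrp1, a melanocyte enzyme, was below the floor on all 3 arrays.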
